A study of Rattus norvegicus with 20 samples.

How the data were processed

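RNA sequencing was carried out on cultures of heart muscle cells isolated from newborn rats and kept for 72 h under 1 of 4 conditions, with 5 samples per condition and 20 in all. The conditions were phosphate-buffered saline (PBS), histidine at 100 nM, doxorubicin at 1 µM, and both compounds together. Group and replicate number were taken from the sample titles, and the columns of the table were matched to samples by the library names in the labels; 0 columns were left without a sample. Per the labels' protocols, RNA was captured on oligo(dT) beads, fragmented, and copied into cDNA from random hexamers by a procedure that does not mark the strand. Reads from a gene and an overlapping or antisense neighbour therefore cannot be told apart, and values of near-identical paralogs are uncertain because reads could be split between them. Trimmomatic and the rat genome build mRatBN7.2 are named in the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here.

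The deposited table held whole-number read counts per gene, not normalised, and a second set of columns with FPKM values, per the file headers. The FPKM values were scaled to the length of the gene and the reads of the library by the authors, per the file headers; the ratio of reads to FPKM followed each library's total reads with a gap of at most 0.009 on the log2 scale over 10528 genes with at least 200 reads. The table held 15503 genes, of which 14326 were protein-coding, and 0 entries that named no gene. The lowest total of a gene over the 20 libraries was 52 reads, and 3010 genes had a mean FPKM under 1, so any earlier filter had left genes of low expression in place. Total counts per library ran from 53246205 to 83624651. All 40 pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 34.7 to 650), so no library was counted as a duplicate.

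Gene coordinates are those of the deposited table. Symbols were taken from a reference gene table of the rat assembly GRCr8, used only for names, through the protein accessions, KEGG names and protein names that the table gave; 10881 genes received a symbol, 7694 through a protein accession, 2738 through a KEGG name, 342 through a symbol inside the protein name, and 107 members of the gene lists through the protein name. Among genes with names from both sources, 4222 of 4233 KEGG names and 827 of 831 symbols in protein names equalled the accession's symbol. Another 20 symbols that fell on more than 1 gene, 42 genes together, were left out as names.

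Counts were filtered with edgeR's filterByExpr, which left 15449 genes, and scaled by trimmed mean of M values (TMM). The main test was edgeR's quasi-likelihood F test in a single fit of the 4 groups over all 20 libraries, without a block for the replicate number, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 5 contrasts were histidine against PBS, doxorubicin against PBS, both against doxorubicin, both against PBS, and the interaction. The SE of a log2 fold change was its size divided by the square root of F. Levels are CPM, counts relative to the library total scaled by TMM, given as mean ± SD over the 5 libraries of a group. Where a group had 0 reads for a gene, its level was bounded by 3 reads over the group; with 1 to 20 reads, a 95% exact Poisson interval is given. Intervals and floors cover counting error only.

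Gene lists were fixed before the data were examined, 41 in all, and the 39 with at least 5 measured members were tested with limma's camera on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01 and again with the correlation estimated for each list. Adjusted p-values of lists are Benjamini-Hochberg values over the 39 lists of a contrast. Named genes followed a rule also fixed before the data were examined. It took the 10 largest rises and the 10 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM, groups that did not overlap and a full gene symbol. Where no gene passed it took the 5 smallest p-values, given as not past the test. It added up to 4 members of each described list with the smallest p, and 25 marker genes given in every comparison, of which 23 were measured; Hal and Hrh2 were not analysed here. Some genes that the rule took are not reported here. For both compounds against PBS and for the interaction it took 5 genes per direction. Members of a list that moved against most of it, genes called by DESeq2 where edgeR called 0, and genes of the closing observations were named after their values were seen.

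The procedure was tested on simulated counts with 200 genes changed by known folds. In a simulated histidine against PBS comparison over 15424 genes, 53.7% of 67 genes changed 1.5 times, 89.6% of 67 changed 2 times and 97% of 66 changed 4 times were recovered, with 9 false calls (5.33%). In a simulated comparison of both compounds against doxorubicin over 15419 genes the shares were 64.2%, 89.6% and 100%, with 7 false calls (3.98%). A list raised 1.5 times was called in both, at adjusted p-values of 5.25e-66 and 1.3e-56 from camera, and 0 other lists were called. Genes were drawn independently of each other, so the simulation cannot show false calls of lists that come from correlation between genes. It changed only genes above a low floor of level and gave each gene the same spread in all libraries. In the real data deviations of doxorubicin replicate 4 had an SD of 0.778, against 0.427 to 0.48 in the rest of its group. The shares recovered therefore need not hold for genes of lower level or for both compounds against doxorubicin. In other splits of the real libraries a median of 4 lists passed for histidine against PBS. For both compounds against doxorubicin the median was 7.

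The alternatives tried were relative log expression and upper-quartile scaling, DESeq2's Wald test, limma on log2(FPKM + 1), no filter on low counts, a filter of 5 CPM, the replicate number as a block, a fit of only the groups compared, a threshold of 1 on the log2 fold change, and each library left out in turn. Fits without doxorubicin replicates 3 and 4, without doxorubicin replicate 4, without histidine replicate 3, and without genes that stood 8-fold or more below or above the rest of their group in a library were added after the data were seen. Settings meant for a table without counts were not run. A gene called neither in the main test nor under an alternative was counted as keeping its call whatever its sign. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.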

Results

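Gene expression was measured by RNA sequencing in cultures of neonatal rat cardiomyocytes, the contractile cells of the heart, after 72 h with PBS, with histidine, with doxorubicin, or with histidine and doxorubicin together. Histidine is an amino acid from which cells make histamine and carnosine. Doxorubicin is an anthracycline cancer drug that traps topoisomerase II on DNA and is toxic to the heart. The series as a whole concerns plasma histidine and the return of atrial fibrillation after ablation, and this part asks what histidine does to heart cells with and without the drug. Each group held 5 libraries. The labels do not say that these came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Total counts per library were 63561787 to 78204997 with PBS, 53246205 to 71623955 with histidine, 54072746 to 83624651 with doxorubicin and 58226690 to 71856131 with both compounds.

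Transcripts of several cell types were present in the PBS cultures. The 16 fibroblast markers took 11.1% of all counts, and Col1a1, which encodes the main chain of type I collagen, alone stood at 42010 ± 1538 CPM (SD, n = 5). The 12 smooth muscle and pericyte markers took 0.782% of counts, the 15 macrophage and leukocyte markers 0.333% and the 18 cardiomyocyte markers 0.118%. Shares of counts are not shares of cells, but much of the RNA may have come from cells other than cardiomyocytes. A change in these whole-culture libraries therefore cannot be assigned to cardiomyocytes. Changes within cells cannot be told apart here from shifts in the share of cell types. The first principal component held 62.6% of the variance and separated the libraries with doxorubicin (69.2 to 78.7) from those without it (-77.8 to -71.0). The second held 7.4% and set doxorubicin replicate 4 at 107.9 against -18.9 to 9.0 in the other 19 libraries.

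Doxorubicin against PBS, the effect of the drug alone, lowered genes of muscle, immune and dividing cells and raised p53 targets. The cardiac myosin heavy chains Myh7 and Myh6, the motor proteins of the sarcomere, fell 23.8-fold and 16.7-fold, Myh7 from 161 ± 11.9 to 6.76 ± 2.34 CPM and Myh6 from 179 ± 15.04 to 10.7 ± 3.58 CPM (SD, n = 5 per group). The macrophage growth factor receptor Csf1r fell 81.1-fold and the proliferation marker Mki67 10.2-fold, from 183 ± 10.4 to 18.0 ± 6.51 CPM. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, rose 6.68-fold from 160 ± 10.9 to 1070 ± 200 CPM, and the stress hormone gene Gdf15 rose 9.21-fold from 9.05 ± 1.69 to 83.4 ± 7.38 CPM. In the quasi-likelihood test 6673 of 15449 genes (43.2%) passed, 3353 higher and 3320 lower. The groups did not overlap for 4810 genes (31.1%), against 0.794% by chance.

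Among the 10 largest rises, Cst6, which encodes the protease inhibitor cystatin M, rose most, 71.1-fold from 0.269 ± 0.154 to 19.4 ± 4.50 CPM, with a log2 fold change of 6.15 ± 0.35 (SE) and an adjusted p of 2.59e-11. The gene, ENSRNOG00000020455, lies on the minus strand of chromosome 1 at 202655322 to 202657030 in mRatBN7.2. Next came Pla2g2a, a secreted phospholipase of inflammation, at 33.2-fold (5.24 ± 2.64 to 175 ± 89.3 CPM), Upk1b at 22.9-fold and Efemp1, a matrix glycoprotein, at 21.7-fold. The log2 fold changes of Pinlyp, Dsc3, Ltk, Serpinb2 and Galnt13 were 4.37 ± 0.22, 4.22 ± 0.41, 3.88 ± 0.26, 3.67 ± 0.63 and 3.60 ± 0.17. Nqo1, an antioxidant enzyme, rose 13.1-fold from 33.6 ± 3.84 to 439 ± 102 CPM. Serpinb2 came to 2.85 without doxorubicin replicate 3.

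Among the 10 largest falls, Gna15 (ENSRNOG00000005378, chromosome 7, 8184861 to 8205508, plus strand), a G protein subunit of blood cells, went from 10.1 ± 1.35 CPM to 0 reads in all 5 libraries, at least 1109-fold lower against a floor of 3 reads over the group. The cytokine Tnf went from 20.6 ± 1.64 CPM to 5 reads over the group, all in replicate 1, a ratio of 1371 with a counting interval of 587 to 4222. Tnfrsf14, Cx3cr1, the class II antigen gene RT1-DMb, Prkcb, Mrgprx3, Clec4a3 and Cd33 fell, with log2 fold changes of -9.34 ± 0.39, -8.72 ± 0.47, -8.66 ± 0.49, -8.23 ± 0.52, -8.09 ± 0.53, -8.05 ± 0.55 and -8.05 ± 0.49. Pik3cg, a lipid kinase of leukocytes, fell from 185 ± 5.99 to 0.672 ± 0.188 CPM. With so few reads left, single libraries moved some of these values. Without doxorubicin replicate 1 Tnf had 0 reads, so its fall has only a lower bound, and RT1-DMb was at -9.26. Without doxorubicin replicate 4 Mrgprx3 was at -9.45.

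Muscle and leukocyte marker genes fell as groups. Of the 18 cardiomyocyte markers 16 fell (median -2.08, adjusted p = 9.24e-12 from camera), and their sum went from 1176 ± 53.7 to 244.9 ± 52.95 CPM. Of the 33 sarcomere genes 26 fell (median -1.99, adjusted p = 7.04e-12), among them Actc1, cardiac actin, 5.63-fold, Tnnt2, troponin T, 3.1-fold, and titin (Ttn) by 2.14 ± 0.14. The thin filament gene Neb (4.17 ± 0.47, 0.196 to 3.49 CPM) and the small heat shock protein gene Cryab (0.39) rose. Of the 15 macrophage and leukocyte markers 14 fell (median -5.58, adjusted p = 1.10e-14), with Ptprc, the pan-leukocyte antigen CD45, down 86-fold, Itgam 83-fold and the lysosomal macrophage protein gene Cd68 20.6-fold. Their sum went from 3331 ± 97.0 to 233.5 ± 56.3 CPM. All 3 groups passed with an estimated correlation, at adjusted p-values of 0.005, 0.0105 and 0.00391.

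Genes of dividing cells fell and p53 targets rose. Of 37 cell cycle genes 36 fell (median -3.03, adjusted p = 6.78e-28; adjusted p = 0.0317 with an estimated correlation), including the mitotic genes Ccnb1 11.8-fold, Cdc20 10.4-fold, Bub1 8.41-fold and Prc1 by 3.31 ± 0.16. Tyms, thymidylate synthase, rose by 0.34 ± 0.07. The drug's target in dividing cells, topoisomerase Top2a, fell 8.85-fold, and the isoform found in resting cells, Top2b, fell by 0.40 ± 0.08. Of 34 p53 targets 22 rose and 5 fell (median 0.66, adjusted p = 1.03e-05; adjusted p = 0.00162 with an estimated correlation), and 22 rose and 6 fell adjusted over the list alone. Mdm2, the ubiquitin ligase that holds p53 in check, rose 4.39-fold, Plk2 by 1.25 ± 0.07 and Aen, an exonuclease of apoptosis, by 0.95 ± 0.05. The p53 targets that fell were Sesn1 (-0.69 ± 0.11), Psrc1 (-0.50 ± 0.14), Ckap2 (-0.31), Plk3 (-0.28) and Ccnk (-0.21). The last 3 passed near the threshold, and their calls ended when any of several libraries was left out. Ckap2 did not pass when any of 8 of the 10 libraries was left out, all except PBS replicate 3 and doxorubicin replicate 3, with an adjusted p of up to 0.084 without doxorubicin replicate 4. Plk3 did not pass without PBS replicate 3 or doxorubicin replicate 2 or 3 (up to 0.0612), and Ccnk without PBS replicate 2, 4 or 5 or doxorubicin replicate 3 or 4 (up to 0.108).

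Of 22 amino acid transporters 14 fell and 2 rose (median -0.44, adjusted p = 0.00222; adjusted p = 0.0317 with an estimated correlation), and 15 fell adjusted over the list alone. In this list Slc7a8 fell by 2.17 ± 0.21, Slc1a5 by 0.71 ± 0.08 and Slc7a5, which carries histidine among other large amino acids, by 1.05 ± 0.12. The rises were Slc38a3, another carrier of histidine and glutamine (3.05 ± 0.35), and Slc43a2 (0.27), which did not pass without PBS replicate 1, 2 or 5 or doxorubicin replicate 3 or 4 (adjusted p up to 0.0723). The carnosine-cleaving enzymes Cndp1 and Cndp2 fell by 5.02 ± 0.40 and 0.80 ± 0.06. Over the 17 genes of histidine, histamine and carnosine metabolism, 7 fell and the list did not pass (adjusted p = 0.0846). Hars1, the histidyl-tRNA synthetase, changed by 0.09 ± 0.05 and did not pass.

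Another 10 lists passed with the preset correlation and not with an estimated one. Of 28 NRF2 and antioxidant genes 17 rose and 2, Ucp2 (-0.63) and Hmox1 (-0.35 ± 0.13), fell (adjusted p = 0.00104; adjusted p = 0.224 with an estimated correlation), and Hmox1, heme oxygenase, did not pass without PBS replicate 3 or 4 or doxorubicin replicate 1, 2 or 3 (up to 0.128). Gsta1, a glutathione transferase, rose by 2.35 ± 0.24. The drug efflux pump genes Abcb1b and Abcb1a, of the list of doxorubicin targets and transport, which did not pass, rose 8.62-fold and by 2.65 ± 0.20. Of 31 fatty acid oxidation genes 16 rose, and Cd36 (-1.52), Lpl (-0.68) and Ppargc1b (-1.17) fell (adjusted p = 0.00551; adjusted p = 0.181 with an estimated correlation). Of 31 interferon-stimulated genes 17 fell, among them the antiviral genes Oas3 (-5.75 ± 0.65) and Mx1 (-3.88 ± 0.36), while Gbp2 (0.98 ± 0.07), Gbp5 (0.48), Tap1 (0.53) and Ifi44l (0.65) rose (adjusted p = 0.00104; adjusted p = 0.384 with an estimated correlation). Leukocyte markers fell in the same libraries (median -5.58). Of 29 senescence-associated secreted factors 17 rose and 6 fell (adjusted p = 0.0413; adjusted p = 0.545 with an estimated correlation), and the list did not pass without doxorubicin replicate 4 (adjusted p = 0.061). The cytokine gene Il6 rose 10.6-fold. Csf1, Il18 and Ccl4 are not in this list but in that of inflammatory and NF-kB genes, which did not pass. Csf1, the macrophage growth factor, rose by 1.82 ± 0.11, whereas the leukocyte cytokines Il18 and Ccl4 fell by 5.47 ± 0.23 and 6.55 ± 0.46.

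With the preset correlation, structural, calcium-handling and biosynthetic groups were lower. Of 12 smooth muscle and pericyte markers 9 fell, among them calponin Cnn1 (-2.27 ± 0.16), Rgs5 (-3.63 ± 0.38) and the contractile actin gene Acta2 (-1.33 ± 0.16), and the channel subunit gene Abcc9 rose (0.53; adjusted p = 0.00104; adjusted p = 0.224 with an estimated correlation). Of 18 fetal heart and remodelling genes 11 fell, including the natriuretic peptide genes Nppb (-1.71 ± 0.26) and Nppa (-1.27 ± 0.25), and Gdf15, Clu (0.85) and Uchl1 (1.06) rose (adjusted p = 0.00648; adjusted p = 0.25 with an estimated correlation). Of 25 calcium-handling genes 12 fell, with the ryanodine receptor Ryr2 at -2.30 ± 0.24, calsequestrin Casq2 at -2.15 ± 0.23 and the calcium pump Atp2a2 at -0.29 ± 0.07, while Cacna1d (1.54) and Asph (0.35) rose (adjusted p = 0.0276; adjusted p = 0.224 with an estimated correlation). Of 27 DNA damage and repair genes 13 fell, among them Fancd2 (-2.22 ± 0.17), Parp1 (-0.75) and H2ax (-1.58 ± 0.09), and Gadd45a (0.84) and Xrcc1 (0.75) rose (adjusted p = 0.00648; adjusted p = 0.158 with an estimated correlation). Of 27 ATF4 targets 12 fell, among them Psat1 of serine synthesis (-1.21 ± 0.09), and Gdf15, Sesn2 (0.66) and Cebpb (0.78) rose (adjusted p = 0.0107; adjusted p = 0.545 with an estimated correlation). Cebpb did not pass without PBS replicate 1, 2, 4 or 5 or doxorubicin replicate 4, and came to 0.18 without the last (adjusted p = 0.339). Of 26 cholesterol and lipid synthesis genes 15 fell, including the desaturase Scd (-2.09 ± 0.18) and Stard4 (-1.44 ± 0.10; adjusted p = 0.00104 for the list; adjusted p = 0.465 with an estimated correlation). Cardiomyocyte markers fell in these libraries too (median -2.08).

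The other 23 lists did not pass. Within the 25 ion channel and gap junction genes 11 fell, including Kcnj2, the inward rectifier (-2.04 ± 0.11), and Kcnk2 rose by 1.66 ± 0.11 (adjusted p = 0.323). Of the 29 inflammatory and NF-kB genes 14 rose and 8 fell (median 0.49, mean -0.59, adjusted p = 0.439), of 48 nuclear-encoded oxidative phosphorylation genes 11 rose (adjusted p = 0.235), and the 13 mitochondrially encoded genes did not pass as a list (adjusted p = 0.654). Of 35 collagen and matrix genes 15 fell and 8 rose (adjusted p = 0.217), with Col1a1 at -0.79 ± 0.13 and the gelatinase Mmp2 at 1.25 ± 0.07. Of 24 genes near atrial fibrillation loci 10 fell and 6 rose (median 0.04, mean -0.35, adjusted p = 0.33). The gap junction gene Gja1 was at 0.76 ± 0.82, the histidine decarboxylase Hdc at 0.61 ± 0.83 and the histamine receptor Hrh1 at -1.70 ± 0.95, and none of the 3 passed.

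**Figure D1:**
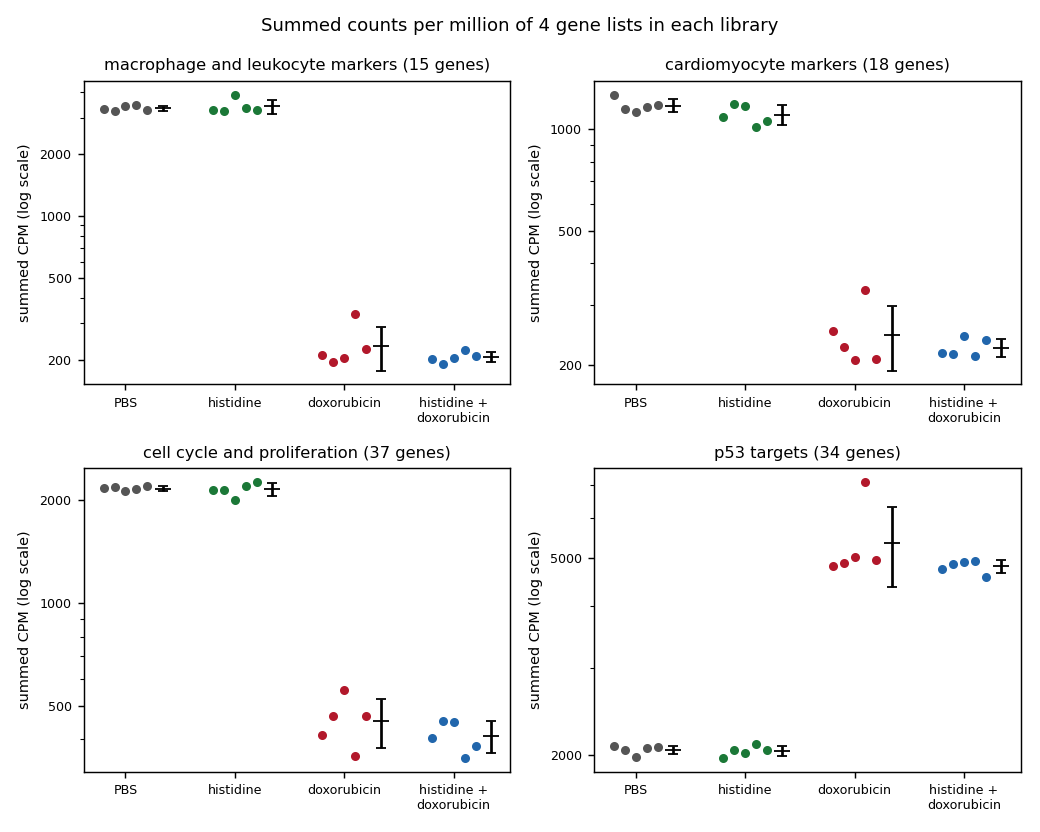
Summed CPM (log scale) of leukocyte, cardiomyocyte, cell cycle and p53 target genes in each library, by group; dots are the 5 libraries of a group and bars the mean ± SD. The leukocyte sum lies near 3331 CPM with PBS and 233.5 CPM with doxorubicin, and doxorubicin replicate 4 lies highest of its group for the leukocyte, cardiomyocyte and p53 sums.

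Histidine against PBS, the effect of the amino acid alone, gave 0 genes past edgeR's test, with 312 at an unadjusted p under 0.05, 5 called by DESeq2 and 0 by limma on FPKM. The log2 fold change was 0.01 ± 0.10 for Cdkn1a, -0.28 ± 0.16 for Myh7, -0.18 ± 0.19 for Myh6, 0.11 ± 0.25 for Nppa, -0.14 ± 0.14 for Gdf15, 0.22 ± 0.28 for Il6 and -0.03 ± 0.12 for Slc7a5 (SE, n = 5 per group). Histidine replicate 3 weighed on Il6, at 27.2 CPM against 7.8 to 9.9 CPM in the other histidine libraries. With PBS too, Il6 was highest in replicate 3. As groups, interferon-stimulated genes were higher by camera (adjusted p = 1.53e-09; adjusted p = 0.282 with an estimated correlation) and immediate-early genes, the first transcription factors a stimulus induces, lower (adjusted p = 8.85e-07; adjusted p = 0.073 with an estimated correlation). Of the 31 interferon-stimulated genes 30 were higher (median 0.17), and their sum was 1172 ± 74.8 CPM with histidine and 1047 ± 61.5 CPM with PBS. All 22 immediate-early genes were lower (median -0.11), with Egr1 at 185 ± 14.6 against 248 ± 21.9 CPM.

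These were the 2 lists that passed with the preset correlation, and neither did with an estimated one. With the replicate number as a block 12 lists passed, these 2 and 10 more at adjusted p-values of 0.00852 to 0.0397 (0.0517 to 0.132 without the block, and 0.282 or more with an estimated correlation). Of the 10, inflammatory, fatty acid oxidation, oxidative phosphorylation and NRF2 genes were higher, and collagens, smooth muscle markers, sarcomere genes, ion channels, adrenergic signalling and Schwann and neuronal markers lower. No member of either passed edgeR's test over all genes. Adjusted over the list alone, 4 immediate-early genes passed, namely Egr1 (-0.42 ± 0.11), the nuclear receptor Nr4a1 (-0.45 ± 0.13), Jun (-0.18 ± 0.06) and Fos (-0.50 ± 0.17). The interferon genes with the smallest p were Gbp5 (0.20 ± 0.07), Xaf1 (0.28 ± 0.12) and Irgm (0.22 ± 0.10), each with an adjusted p of 1. Leukocyte markers were at 3406 ± 265 CPM with histidine (adjusted p = 0.831 for the list). The 17 genes of histidine, histamine and carnosine metabolism had 9 members higher (adjusted p = 0.895). Without histidine replicate 3, 9 lists passed, the interferon and immediate-early lists among them.

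Of the 312 genes at an unadjusted p under 0.05, 133 were higher and 179 lower, and chance gives 772. The count was 667 with only PBS and histidine fitted and 697 without doxorubicin replicates 3 and 4. It was 278 to 387 with a PBS or histidine library left out. The low count therefore depended on the doxorubicin libraries in the shared fit and is no measure of a missing effect. Genes past the test were 0 with only the 2 groups and 1 without doxorubicin replicates 3 and 4. The groups did not overlap for 130 genes (0.841%, chance 0.794%). The smallest p belonged to Tspan8, a tetraspanin (ENSRNOG00000004411, chromosome 7, 51445074 to 51479356), with 2 reads over the PBS group and 0.156 ± 0.0365 CPM with histidine (adjusted p = 0.105, and 0.0454 without PBS replicate 4). Ldah, a lipid droplet hydrolase (ENSRNOG00000021475, chromosome 6, 31082055 to 31166618), was at 1.87 ± 0.289 CPM with histidine and 16.7 ± 8.75 CPM with PBS (-3.15 ± 0.60, adjusted p = 0.361, and 0.0154 without PBS replicate 3). It stood as low in PBS replicate 3 (1.57 CPM) and doxorubicin replicate 5 (1.40 CPM). ENSRNOG00000070111, annotated as apolipoprotein L2, followed at -1.17 ± 0.25 (adjusted p = 0.876), then Dmrt2 at 1.01 ± 0.23 and Nlgn3 at -0.81 ± 0.19. The 5 genes of DESeq2 were Tspan8, Ldah, ENSRNOG00000070111, the long noncoding ENSRNOG00000067929 (0.585 ± 0.615 CPM with PBS, 0 reads with histidine) and ENSRNOG00000030719 (0 reads with PBS, 0.0838 ± 0.0958 CPM with histidine).

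**Figure D2:**
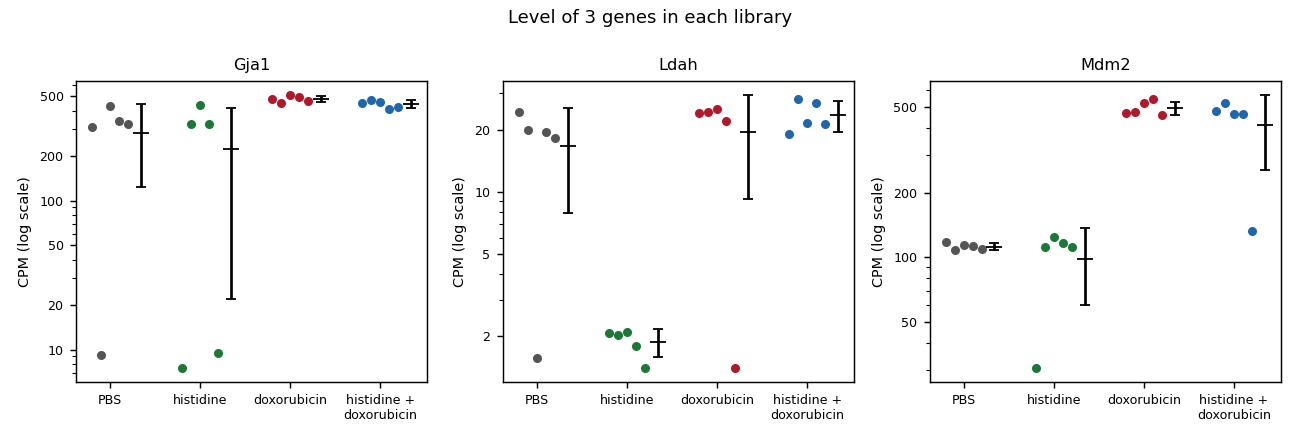
CPM (log scale) of Gja1, Ldah and Mdm2 in each library, by group; dots are the 5 libraries and bars the mean ± SD. Gja1 stands at 9.13 CPM in PBS replicate 2 and at 7.50 and 9.52 CPM in histidine replicates 1 and 5, and Ldah is low in all 5 histidine libraries, PBS replicate 3 and doxorubicin replicate 5.

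Histidine with doxorubicin against doxorubicin, the effect of histidine in drug-treated cells, gave 0 genes past edgeR's test. At an unadjusted p under 0.05 there were 1940, against 772 by chance. DESeq2 called 20 and limma on FPKM 0. By camera 13 lists passed with the preset correlation and 0 with an estimated one (adjusted p = 0.537 with an estimated correlation for each of the 13). Of the 37 cell cycle genes, already low with the drug, 31 were below doxorubicin alone (median -0.25). Of the 29 senescence-associated secreted factors 28 were lower (median -0.42), among them the chemokine gene Ccl2 (-0.83 ± 0.30, and -0.39 without doxorubicin replicate 4) and the urokinase receptor Plaur (-0.53 ± 0.16). Of the 48 nuclear-encoded oxidative phosphorylation genes 45 were lower (median -0.30), a list that did not pass without doxorubicin replicate 4 (adjusted p = 0.0605). Chaf1b, a histone chaperone subunit of DNA replication (ENSRNOG00000001692, chromosome 11, 33200981 to 33221070), was at 2.97 ± 0.315 against 4.74 ± 0.837 CPM (-0.68 ± 0.11; SE, n = 5 per group). Of the marker genes, Cdkn1a was at -0.17 ± 0.10 (-0.04 without doxorubicin replicate 4), Myh7 at 0.18 ± 0.16 and Mdm2 at -0.26 ± 0.31 (-0.03 without replicate 5 of both compounds), and none of the 3 passed.

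Of the 1940 genes at an unadjusted p under 0.05, 662 were higher and 1278 lower. The excess over the 772 of chance depended on the libraries fitted. The count was 767 with only these 2 groups fitted and 787 without doxorubicin replicates 3 and 4. With a library left out it was 1127 to 2807, lowest without doxorubicin replicate 4. The 20 of DESeq2 were 6 higher and 14 lower, and edgeR called up to 6 with a library left out (6 without doxorubicin replicate 2). The groups did not overlap for 163 genes (1.06%, chance 0.794%). The 5 smallest p-values belonged to Chaf1b and ENSRNOG00000007706, annotated as the AMP-activated protein kinase subunit alpha-2 (0.60 ± 0.10), both at an adjusted p of 0.077, and to Ly86, LOC681325 and the mitotic gene Cdca2 (-0.53 ± 0.10) at 0.139, 0.159 and 0.167. Ly86, a gene of macrophages and B cells, and LOC681325 had 0 reads with both compounds and 0.137 and 0.122 CPM with doxorubicin. Several of these passed when a library was left out: Chaf1b without doxorubicin replicate 1, 2 or 4 or replicate 5 of both compounds (0.0402 without doxorubicin replicate 4), Cdca2 and ENSRNOG00000007706 without doxorubicin replicate 4, LOC681325 without doxorubicin replicate 1 (0.00593) and Ly86 without doxorubicin replicate 2 (0.00324). Nppb, the B-type natriuretic peptide gene, was at -0.87 ± 0.26 and Il6 at -0.58 ± 0.28, at adjusted p-values of 0.394 and 0.398.

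Of the 13 lists past the test with the preset correlation, 4 were higher and 9 lower, and 0 passed with an estimated one (adjusted p = 0.537 with an estimated correlation for each). The lower lists were oxidative phosphorylation (adjusted p = 2.91e-07), cell cycle (1.08e-06), glycolysis (21 of 26 lower, 2.87e-05), senescence-associated factors (2.87e-05), inflammatory and NF-kB genes (27 of 29, 0.00117), cytosolic ribosomal proteins (10 of 10, 0.00174), NRF2 and antioxidant genes (22 of 28, 0.0021), fatty acid oxidation (25 of 31, 0.00404) and autophagy and lysosome (18 of 24, 0.0344). The higher lists were collagens and matrix (27 of 35, 0.00189), smooth muscle and pericyte markers (10 of 12, 0.0059), adrenergic and natriuretic signalling (18 of 26, 0.00734) and fibroblast markers (11 of 16, 0.0344). Members with the smallest p included the mitotic genes Birc5 (-0.75 ± 0.17) and Cdk1 (-0.52 ± 0.13), the glycolytic enzymes Gapdh (-0.35 ± 0.12) and Aldoa (-0.33 ± 0.11), the respiratory chain gene Cox7b (-1.03 ± 0.37) and the fibroblast genes Pdgfra (0.54 ± 0.20) and Postn (0.34 ± 0.14). Without doxorubicin replicate 4 Cox7b was at -0.11 and Gapdh at -0.19, and without replicate 3 of both compounds Aldoa was at -0.22. Adjusted over the list alone, 5 cell cycle genes passed: Birc5, Cdk1, Ttk (-0.59 ± 0.16), Ccnb2 (-0.77 ± 0.22) and Cdc20 (-0.45 ± 0.14). Leukocyte markers were not among the 13 lists. Their sum was 205.5 ± 11.5 CPM with both compounds and 233.5 ± 56.3 CPM with doxorubicin. Doxorubicin replicate 4 stood at 332.2 CPM, against 194.8 to 226 CPM in the rest of its group.

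Doxorubicin replicate 4, which stood apart from its group, weighed on part of this. Without it 12 lists passed. The lists of oxidative phosphorylation (adjusted p = 0.0605), ribosomal proteins (0.876), NRF2 (0.0541) and autophagy (0.264) did not pass, whereas cell cycle (7.96e-20), glycolysis (4.49e-06), senescence-associated factors (0.000382), inflammatory genes (1.58e-05), fatty acid oxidation (0.0059), collagens (0.00529), smooth muscle markers (0.00529), fibroblast markers (0.00173) and adrenergic signalling (0.0479) did, and doxorubicin targets and transport (lower, 0.0479), interferon-stimulated genes (higher, 0.0479) and mitochondrially encoded genes (higher, 0.0497) passed in that fit. Without doxorubicin replicates 3 and 4, 6 lists passed, namely cell cycle, glycolysis, inflammatory genes and fatty acid oxidation again, mitochondrially encoded genes (higher, 0.00254) and immediate-early genes (lower, 0.0133).

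Histidine with doxorubicin against PBS, the effect of both compounds together, raised and lowered many of the genes that doxorubicin alone did. Cst6 rose 52.4-fold and Pla2g2a 21.5-fold, followed by Efemp1 (4.42 ± 0.22), Upk1b (4.32 ± 0.23) and Pinlyp (4.08 ± 0.22; SE, n = 5 per group). Cdkn1a rose 5.95-fold, Gdf15 8.15-fold, Mdm2 by 1.88 ± 0.32 and Il6 7.11-fold, while Myh7 fell 21.1-fold, Myh6 by 4.05 ± 0.21, Mki67 12.3-fold, Top2a by 3.44 ± 0.27, Nppb by 2.57 ± 0.27, Ryr2 by 1.94 ± 0.24 and Acta2 by 1.18 ± 0.16. The 5 largest falls came down to a few reads. Tnf and Gna15 had 0 reads, at least 2289-fold and 1111-fold lower, and Lst1 had 3 reads (ratio 2130, counting interval 729 to 10326), Mrgprx3 4 reads (1905, 744 to 6991) and the complement gene C1qb 12 reads (1237, 708 to 2395). Single libraries weighed on these values. All reads of Lst1 lay in replicate 5 and all reads of Mrgprx3 in replicate 4 of both compounds. Without that library each had 0 reads, and the fall has only a lower bound. For C1qb the log2 fold change was -11.33 without replicate 4 of both compounds.

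In edgeR's test 6166 genes (39.9%) passed, 2968 higher and 3198 lower, and the groups did not overlap for 5871 genes (38%, chance 0.794%). Of the 15 lists that passed, 3 higher and 12 lower, 6 did so with an estimated correlation: cardiomyocyte markers (17 of 18 fell, adjusted p = 0.00312 with an estimated correlation), leukocyte markers (14 of 15, median -6.02, 0.00275), cell cycle (36 of 37, 0.0274), sarcomere (27 of 33, 0.00963), p53 targets (19 rose, 0.00126) and amino acid transporters (14 of 22 fell, 0.044). The other 9 were interferon-stimulated genes, cholesterol synthesis, fetal heart genes, smooth muscle markers, ATF4 targets, DNA damage genes and glycolysis (lower), and NRF2 and fatty acid oxidation genes (higher), with adjusted p = 0.31 to adjusted p = 0.585 with an estimated correlation. Top2b fell by 0.22 at an adjusted p of 0.0469 that rose above the threshold in 8 of 10 fits with a library left out, all except those without PBS replicate 3 or replicate 2 of both compounds, and up to 0.125 without replicate 3 of both compounds. Hrh1, not past the test at -2.0 (adjusted p = 0.113), passed without replicate 2 of both compounds (-4.24, adjusted p = 0.004).

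Of the genes called with doxorubicin alone and with both compounds, 2434 were higher in both comparisons and 2756 lower in both, and 0 went opposite ways. Independent lists of these sizes would share 644 and 687. In 20 simulations of unchanged groups, with a simulated PBS group common to both comparisons, 0 calls were shared. Unchanged groups leave few calls to share, so this does not measure how a common PBS group adds to the overlap. With the PBS libraries split between the comparisons in 10 ways, a mean of 1522 higher (1452 to 1587) and 2175 lower genes (2096 to 2239) were shared.

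**Figure D3:**
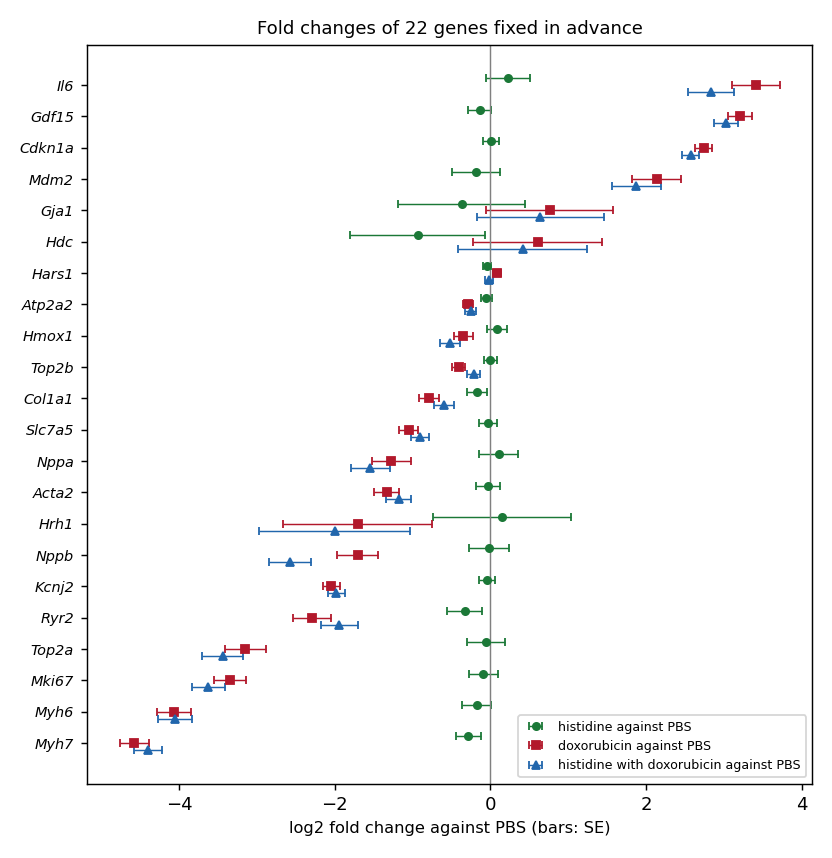
Log2 fold change against PBS of 22 genes chosen before the data were examined, for histidine, doxorubicin and both compounds; symbols are estimates over 5 libraries per group and bars the SE. Histidine alone lies near 0 (Cdkn1a 0.01, Myh7 -0.28), and the values with doxorubicin and with both compounds lie close together (Cdkn1a 2.74 and 2.57, Myh7 -4.58 and -4.40).

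The interaction asks whether histidine acted differently with and without the drug. The marker genes gave no call: Cdkn1a was at -0.18 ± 0.14, Myh7 at 0.46 ± 0.23, Nppb at -0.85 ± 0.36 and Il6 at -0.81 ± 0.39, or -0.30 without histidine replicate 3 (log2 difference of the histidine effects ± SE, n = 5 per group). The 5 smallest p-values belonged to Tspan8 (-5.0 ± 0.85, adjusted p = 0.167), ENSRNOG00000007706 (0.75 ± 0.14), Chaf1b (-0.78 ± 0.15), LOC681325 and ENSRNOG00000070111 (1.83 ± 0.36), the last 4 at an adjusted p of 0.189. ENSRNOG00000070111 passed without doxorubicin replicate 5 (0.0389) and LOC681325 without doxorubicin replicate 1, and 2 genes passed without doxorubicin replicate 2. In edgeR's test 0 genes passed, with 1060 at an unadjusted p under 0.05 (531 higher, 529 lower), where chance gives 772. The excess over chance depended on the libraries fitted. The count was 715 without doxorubicin replicates 3 and 4. With a library left out it was 740 (without histidine replicate 4) to 1743 (without doxorubicin replicate 1). DESeq2 called 15 and limma on FPKM 0. By camera 13 lists passed, 4 higher and 9 lower, and 0 with an estimated correlation (adjusted p = 0.498 with an estimated correlation at the lowest). Oxidative phosphorylation genes (46 of 48 lower, adjusted p = 2.82e-07) and senescence-associated factors (27 of 29 lower, 8.99e-05) had the smallest adjusted p among the lower lists, and collagens and matrix (28 of 35 higher, 0.000233) among the higher ones.

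Across genes, which are not independent replicates, the histidine effects without and with doxorubicin had a Pearson correlation of -0.0767 and a Spearman correlation of -0.167. With relabelled libraries the Spearman value ran from -0.205 to 0.273, a range that holds the real one. The Pearson value ran from -0.0751 to 0.0832, and 2 of 100 relabellings, the real one included, were as far from 0. The effect of histidine in drug-treated cells against the effect of doxorubicin had a Pearson correlation of -0.137 and a covariance of -0.0692. The 2 effects share the doxorubicin libraries, and 20 simulations of unchanged groups gave a mean correlation of -0.501 and a covariance of -0.0501, so that the covariance difference was -0.0191. The simulations gave all groups the same spread, whereas deviations in doxorubicin replicate 4 had an SD of 0.778 against 0.427 to 0.48 in the rest of its group. The difference therefore cannot be read as what remains beyond the shared libraries. With the doxorubicin libraries split between the effects, the mean over 10 splits was -0.041 for the correlation (-0.111 to 0.0227) and -0.0323 for the covariance.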

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

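The tests of a mislabelled library and of scaling between groups, the definition of genes low in single libraries, and the fits without doxorubicin replicates 3 and 4, doxorubicin replicate 4 or histidine replicate 3 were chosen after the results were seen; the other tests were not.

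Doxorubicin replicate 4 stood apart from the other doxorubicin libraries, with a spread of its gene deviations of 0.973 (SD, log2). Removing a smooth trend on gene length left an SD of 0.887 against 0.456 to 0.593 in the other 19 libraries, which argues against length bias as the whole cause. The deviation did follow gene length, with a Spearman correlation of -0.507 against -0.268 to 0.383 in the other 19 libraries. Length bias as part of the cause therefore stays open. The library carried the drug response in full, with a median signed change of 0.641 over 7294 called genes against 0.566 to 0.658 in the other doxorubicin libraries (ratio 1.07 to them), which argues against a mislabelled library from a group without the drug. Cells of another type in that culture may account for part of it and cannot be told apart from other causes here: cardiomyocyte markers deviated by a median of 0.88 and leukocyte markers by 0.459, but quartiles of the first ran from -0.212 to 1.05, and endothelial markers lay at -0.511. A difference in the culture itself stays open and was not tested.

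Single genes fell to an eighth or less of their group's level in 1 library, while others of the group did not. There were 351 such cases in 142 genes, 10 to 29 per library, and 84 of the genes did so in more than 1 library; Gja1 was among them. A variant shared by libraries of the same replicate number is argued against, since 67 of 356 pairs of low cases in different groups had the same number, against a median of 71 in 1000 shuffles. A candidate explanation is the assignment of reads between overlapping genes, since 42.1% of the genes (59 of 140) overlapped another gene, against a median of 20% and an upper limit of 27.1% in 1000 random lists matched on level. Another gene model or length in that library stays open, because only 76.4% of the cases gave an implied length (median absolute log2 ratio 0.0315) and that test was void; beyond the shared variant, no biological explanation was tested.

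Leukocyte transcripts were lower in both doxorubicin groups. Scaling between groups is argued against as the cause, because the median change of the 15 markers was -5.58, -5.57 and -5.57 under 3 scalings and -5.56 without any. A candidate explanation is that fewer of the cells that carry these transcripts were left, since 81% (34 of 42) of a second list of leukocyte genes, none of them in the first, were lower by over 2 past the test, and 39 of the 42 were lower past the test at a median of -5.28. Of that list 1 gene was higher past the test, and 34 were also lower by over 2 with both compounds. Lower expression of these genes in the same number of cells was not tested.

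Other splits of the same libraries were drawn 100 times per result, the real split included. Only the real split reached the count of genes changed by doxorubicin (6673, highest other split 1387, 1 split as large). The same held for both compounds against PBS (6166, highest other 1, 1 split as large). This covers chance splits of these libraries only. The labels do not say that the libraries came from separate cultures, so a chance difference between cultures cannot be excluded. The split with 1387 genes set doxorubicin replicates 1, 2, 3 and 5 with PBS replicate 2 against the rest, so it kept 4 of the 5 drug libraries together. With a real count of 0 genes every split is as large, so the splits decide nothing for histidine against PBS (highest other 1, 100 splits), both compounds against doxorubicin (highest other 40, 100 splits) and the interaction (highest other 2, 100 splits). The split with 40 genes set doxorubicin replicates 2, 3, 4 and 5 with replicate 3 of both compounds against the rest. It kept 4 of the 5 libraries of each group together, so a structure of the samples that it points to cannot be separated here from the effect of histidine. Of the 5 counts of gene lists, that of the interaction alone was reached by under 0.05 of the splits (13 lists, 4 splits), though another split gave 15 and 0 of the lists passed with an estimated correlation. Chance cannot be excluded for the counts of histidine against PBS (2 lists, highest other 13, 65 splits) and both compounds against doxorubicin (13 lists, highest other 14, 6 splits). For doxorubicin against PBS (16 lists, highest other 19, 14 splits) and both compounds against PBS (15 lists, highest other 16, 7 splits), splits that part the drug libraries unevenly still carry the drug's effect, so they are no reference without a change and say nothing about single lists such as cell cycle.

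A library far from the other 4 of its group was found for 77 of 596 tested sets of 5 values, by a gap to its neighbour of over 0.71 of the group's range, where chance gives about 1 in 20, or 30. The sets were those of 140 genes reported here and of some sums, and some genes were named after their values were seen. A gene with reads in only 1 library of a group gives a ratio of 1 by construction, as for Tnf, Mrgprx3, Lst1, Tspan8 and Slc4a1 below. The excess over 30 is therefore no test of how often libraries stand apart. Histidine replicate 3 held 16 of them, with ratios of 0.963 for Pla2g2a and Ccl2, 0.892 for Il6, 0.89 for Scd, 0.877 for LOC681325, 0.845 for Psat1, 0.842 for Serpinb2, 0.829 for Slc43a2, 0.809 for Nppb, 0.798 for Nqo1, 0.775 for Hmox1, 0.763 for Klf4, 0.761 for Itgam, 0.739 for Cacna1d, 0.715 for Abcb1b and 0.831 for the leukocyte sum. Doxorubicin replicate 4 held 15, with 0.964 for Gsta1, 0.955 for Cox7b, 0.922 for Cebpb, 0.907 for Tspan8, 0.855 for Cacna1d, 0.828 for Nppa, 0.8 for Ccnk, 0.795 for Cdkn1a, 0.781 for Cryab, 0.761 for Atp5f1b, 0.729 for Fancd2, 0.727 for Gadd45a, 0.715 for Gapdh, 0.904 for the sum of FPKM and 0.773 for the leukocyte sum.

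The other histidine libraries gave 0.865 for Mdm2 in replicate 1, 0.794 for Dmrt2 in replicate 2, 0.734 for Cdk1, 0.747 for Xrcc1 and 0.822 for the sum of FPKM in replicate 4, and 0.793 for Cst6, 0.75 for Csf1r and 0.719 for Cndp2 in replicate 5. With PBS the ratios were 0.796 for Ltk, 0.718 for Il18, 0.766 for H2ax and 0.844 for the mitochondrial share in replicate 1, 0.745 for Mrgprx3, 0.736 for Ldah, 0.788 for Plaur and 0.731 for Uchl1 in replicate 3, 1 for both Tspan8 and Slc4a1 in replicate 4, and 0.764 for Slc7a8 in replicate 5. The other doxorubicin libraries gave 1 for Tnf in replicate 1, 0.789 for Pla2g2a and 0.907 for Serpinb2 in replicate 3, and 0.873 for Ldah, 0.886 for ENSRNOG00000070111 and 0.775 for Sesn2 in replicate 5. With both compounds they were 0.874 for Ahsp in replicate 1, 0.811 for Hrh1, 0.717 for Plk3, 0.749 for Slc43a2, 0.848 for Gadd45a, 0.727 for Xrcc1 and 0.769 for H1f1 in replicate 2, and 0.782 for Cst6, 0.799 for Pla2g2a, 0.716 for Nqo1, 0.799 for Dmrt2, 0.785 for Nlgn3, 0.821 for Aldoa and 0.831 for Ucp2 in replicate 3. Replicate 4 of both compounds gave 1 for Mrgprx3, and replicate 5 gave 0.743 for Tnnt2, 0.846 for Mdm2, 0.724 for Abcb1a, 0.81 for Chaf1b, 1 for Lst1 and 0.77 for Slc38a3.

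The effect of histidine differed with and without doxorubicin for 13 gene lists by camera's test of the interaction, and for none with an estimated correlation (lowest adjusted p 0.498). The adjusted p was 2.82e-07 for oxidative phosphorylation, 8.99e-05 for senescence-associated factors, 0.000126 for cell cycle (31 of 37 lower), 0.000425 for each of fatty acid oxidation (23 of 31 lower), NRF2 (25 of 28 lower) and inflammatory genes (25 of 29 lower), 0.000966 for ribosomal proteins (10 of 10 lower), 0.00381 for glycolysis (20 of 26 lower; 0.0524 without histidine replicate 3) and 0.0226 for interferon-stimulated genes (25 of 31 lower; 0.104 without doxorubicin replicate 4). It was 0.000233 for collagens, 0.000966 for adrenergic signalling (20 of 26 higher) and smooth muscle markers (11 of 12 higher), and 0.0198 for fibroblast markers (11 of 16 higher). Leukocyte markers were not among the 13. Their sum was 3406 ± 265 CPM with histidine and 3331 ± 97.0 CPM with PBS. With the drug it was 205.5 ± 11.5 CPM with histidine and 233.5 ± 56.3 CPM without it.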

How the results depend on the processing

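The fits without doxorubicin replicates 3 and 4, without doxorubicin replicate 4 or histidine replicate 3 for lists, and without genes low or high in single libraries were chosen after the data were seen. How depth alone limits the calls was not tested. In simulated counts 53.7% (histidine against PBS) and 64.2% (both compounds against doxorubicin) of 1.5-fold changes were recovered. The simulation gave each gene the same spread in all libraries, whereas doxorubicin replicate 4 deviated more, so the second share need not hold here. Genes near 0 reads carry wide counting error. The counts of genes changed by doxorubicin (6673) and by both compounds against PBS (6166) stayed within 1.5 times under every other scaling, test, filter and sample choice tried; with a log2 fold change of at least 1 they were 2347 and 2201, by construction, and with each library left out 6028 to 7298 and 5640 to 5871. Histidine against PBS (0) gave 5 with DESeq2, 1 without doxorubicin replicates 3 and 4, and 0 to 1 with a library left out (1 without PBS replicate 3, Ldah, or PBS replicate 4, Tspan8). Both compounds against doxorubicin (0) gave 2 with upper-quartile factors, 20 with DESeq2, 2 with a filter of 5 CPM, 2 without doxorubicin replicates 3 and 4, and 0 to 6 with a library left out (2, 6, 1 and 4 without doxorubicin replicates 1, 2, 3 and 4, 1 without replicate 5 of both compounds). The interaction (0) gave 15 with DESeq2 and 0 to 2 with a library left out (1, 2 and 1 without doxorubicin replicates 1, 2 and 5). The cause of these differences was not tested.

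Gene lists past the test, with the preset and then an estimated correlation, were 2 and 0 for histidine against PBS, 16 and 6 for doxorubicin against PBS, 13 and 0 for both compounds against doxorubicin, 15 and 6 for both against PBS, and 13 and 0 for the interaction. Without histidine replicate 3 histidine against PBS gave 9 lists; without doxorubicin replicates 3 and 4 both compounds against doxorubicin gave 6. The correlation of the histidine effects (-0.0767) was -0.141 with a filter of 5 CPM and -0.118 to -0.0272 with a library left out (lowest without doxorubicin replicate 3, highest without histidine replicate 3); that of histidine against the doxorubicin effect (-0.137) was -0.247 to -0.115 (without doxorubicin replicate 5 and replicate 5 of both compounds). The cause was not tested.

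The replicate number was not taken to pair the libraries, since the correlation of deviations was over 0.1 in 2 of 30 same-number pairs (mean 0.0192, highest 0.193) and not in every pair. It was so in 0 of 120 pairs with different numbers (mean -0.0048, highest 0.0794), and 9 of 20 libraries correlated best with their own number, a hint from the data of a weak shared deviation. With the number as a block the counts were 0, 6579, 0, 6237 and 0 genes in the order above, and 12, 16, 13, 16 and 13 lists. Values for single genes and for single gene lists were counted together over the alternatives. Of these, 12829 kept their side of the threshold, where a gene or list called in neither fit counts whatever its sign. Another 79 came to pass it, 172 no longer passed it, and 0 called values changed sign.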

Other observations

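The genes below were named, and the tests of replicate numbers chosen, after their values were seen. Of 3 measured genes of red blood cells, all low in these cultures, 2 were higher past the test with doxorubicin; the list was too short to test. Slc4a1, the anion exchanger of red cells, rose with doxorubicin from 0.0212 ± 0.0474 to 1.02 CPM (5.37 ± 0.75, SE, adjusted p = 7.51e-06 by edgeR's quasi-likelihood test) and stood at 1.62 CPM with both compounds. Its 8 PBS reads all lay in replicate 4. Without that library PBS had 0 reads, and the rise has only a lower bound. Ahsp, which stabilises alpha globin, went from 0.720 ± 0.082 to 1.11 CPM (0.63 ± 0.23, adjusted p = 0.0364) and did not pass without PBS replicate 1, 3, 4 or 5 or doxorubicin replicate 3 or 4 (up to 0.106), while Alas2, the heme synthesis enzyme of red cells, was at -0.33 and did not pass. The linker histone genes H1f5 and H1f1 were at 0.49 ± 0.18 and 1.75 ± 0.69 with doxorubicin (adjusted p = 0.0299 and 0.0476), whereas cell cycle genes fell. H1f5 did not pass without PBS replicate 1 or 4 or doxorubicin replicate 3 or 5 (up to 0.0829), nor H1f1 without any PBS library or doxorubicin replicate 2, 3 or 4 (up to 0.179).

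Some inflammatory genes, 12 of 29, were highest in replicate 3 of all 4 groups. Over 15449 genes, the highest library carried number 3 in every group for 246 genes, number 4 for 86, number 2 for 32, number 1 for 10 and number 5 for 9, where chance gives 25 per number. With libraries shuffled within groups, 30 of 1000 orders, the real one included, gave a highest count as large (median 41, largest 256). The 246 genes included, of these 12, the chemokines Cxcl1 and Cxcl2, Il6, Nfkbia and Ptgs2, as well as 8 of 29 senescence-associated factors (Cxcl1, Cxcl2 and Il6 again among them), 5 of 26 glycolysis genes, 4 of 28 NRF2 genes and 4 of 31 fatty acid oxidation genes. Pla2g2a stood in replicate 3 at 9.06 CPM with PBS (3.17 to 6.95 in the others), 32.7 with histidine (3.67 to 4.75), 331 with doxorubicin (117 to 162) and 185 with both compounds (85.9 to 106).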
